A study of Mus musculus with 18 samples.

How the data were processed

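RNA sequencing libraries were made from ILC2 sorted from bone marrow and lung. Per the labels, 200 cells were sorted per sample, while the extract protocol speaks of 100 cells per tube, and the sources used here do not settle which number applies. Per the labels' protocols, the cell lysate went straight into reverse transcription with an oligo-dT primer carrying a molecular barcode, a second primer site was added by template switching, and the cDNA was amplified by PCR. ERCC spike-in RNA was added to every tube, per the labels' protocols. The submitters' processing notes name STAR and the mm10 build without versions or roles. The counting tool, the annotation and whether reads were collapsed by molecular barcode are not given in the sources used here.

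The values deposited by the authors are whole-number counts per gene symbol, 1 column for each of the 18 libraries, with no scaling between libraries, as the column totals of 68077 to 122250 show. The table has 24781 gene entries, of which 11836 have no count in any library. It has 0 ERCC entries, so the planned comparison of RNA content against the spike-in was not analysed here. It also has 26 entries whose names are dates, 2 of them repeated, and these were left as they are. Gene positions were taken from GENCODE release M21, and 1886 of the 1916 tested genes (98.4%) matched a single entry there by symbol. Whether the counting used strand is not given in the sources used here, so counts of overlapping genes, antisense genes, pseudogenes and near-identical family members, ribosomal protein genes and Tgtp1 with Tgtp2 among them, are uncertain.

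Samples were grouped by population and genotype as the labels give them, in 6 groups of 3. Counts were scaled with TMM factors, genes with low counts were removed with filterByExpr by group (minimum count 10), and edgeR 4.0.16 in R 4.3.3 was used to fit 6 group means over all 18 libraries. Each comparison was tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over the 1916 genes tested and a threshold of 0.05 on the adjusted p. Differences of CD45 effects between populations were contrasts in the same fit. Standard errors were approximated as the absolute log2 fold change divided by the square root of the F statistic. The square root of the common dispersion was 0.0969. Levels are CPM with TMM-scaled library sizes. Where a group had 0 counts, a fold is a bound against 3 counts over the group.

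Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives not described as chosen later, and the rule for naming genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over 22 lists within a comparison. Camera with an estimated correlation and fry were run beside it. Marker lists of other cell types with fewer tested members were summed as counts. The genes named were Ptprc and a fixed panel of ILC2 genes, up to 8 higher and 8 lower genes with the largest changes among those passing with groups of libraries that did not overlap and a mean of at least 10 counts, up to 4 passing members of each list, and for differences of effects up to 8 passing genes. Predicted gene models were left out by the rule. The text names a part of the genes the rule gives, since some are not reported here, and says where a gene outside it was chosen after its values were seen.

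Alternatives were the size factors of DESeq2, no filter on low counts, a filter of at least 10 counts in 3 libraries, the Wald test of DESeq2 1.42.0, a fit of only the libraries in the contrast, the replicate number as a block, and leaving out each library in turn. Alternatives with spike-in factors were not run. Chosen after seeing the data were fits without the abundant genes Rn45s and Rn4.5s, without the library labelled mature CD45 KO replicate 1 and mature control replicate 1 together, and without genes on chromosomes X and Y.

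The steps were tested on simulated data with 200 changed genes, counts drawn from the means and library sizes of the real libraries and a dispersion of 0.01. Every simulated library had this dispersion, whereas the real library labelled mature CD45 KO replicate 1 lay apart from its group. Recovery in comparisons with mature CD45 KO ILC2 may therefore be overstated. For CD45 KO against control, 4-fold changes were recovered for 86.9% of changed genes tested in mature, 90.8% in immature and 88.0% in lung ILC2, and 2-fold changes for 44.3%, 41.3% and 44.9%. For differences of CD45 effects, 4-fold changes were recovered for 65.6% (lung against mature), 61.8% (mature against immature) and 66.3% (lung against immature), and 2-fold changes for 24.1%, 21.5% and 18.6%. A simulated list of 20 genes higher by 1.4-fold passed in 6 of the 8 comparisons and was missed for the lung against mature and lung against immature differences (adjusted p = 0.153 and 0.128). Intervals of counts are exact Poisson intervals at 95% and cover counting error only, since PCR copies are independent molecules only where molecular barcodes were used. Figures were drawn with matplotlib 3.10.9.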

Results

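Transcripts were counted in group 2 innate lymphoid cells (ILC2), lymphocytes that lack rearranged antigen receptors and secrete type 2 cytokines. The cells came from the lung and bone marrow of control mice and of mice without CD45. CD45 is the receptor tyrosine phosphatase encoded by Ptprc and acts on Src-family kinases. The genotype labels put every mouse on a Rag2-deficient background, which lacks T and B cells. The 18 libraries fell into 6 groups of 3: mature bone marrow ILC2, immature bone marrow ILC2 and lung ILC2, each from CD45 knockout (KO) and control mice. Total counts were 69987, 73968 and 103057 in mature controls and 87335, 122250 and 116708 in mature CD45 KO libraries. They were 87647, 94758 and 84446 in immature controls and 109904, 117933 and 97559 in immature CD45 KO libraries. In lung they were 82941, 87007 and 107373 in controls and 68077, 106753 and 72735 in CD45 KO libraries. Between 7189 and 8793 genes were detected per library, and 1916 genes had enough counts to be tested. The median tested gene had a mean of 12.6 counts per library, and a count of 0 allows a level of up to 44.7 normalised CPM (counts scaled to library size) in the library where the limit is highest, for counting error only. Levels below are normalised CPM as mean ± SD (n = 3), and changes are log2 fold changes ± SE.

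Ptprc, the targeted gene (chromosome 1, 138062861 to 138175708 on the minus strand of the mm10 build, protein coding, ENSMUSG00000026395.16), was lower in all 3 CD45 KO populations. In mature bone marrow ILC2 it fell from 418 ± 148 to 142 ± 83.2 CPM, a log2 change of -1.68 ± 0.29 (adjusted p = 0.00015). In immature ILC2 it fell from 389 ± 65.8 to 93.0 ± 48.5 CPM (-2.01 ± 0.31, adjusted p = 7.9e-06). In lung ILC2 it fell from 579 ± 43.7 to 165 ± 59.7 CPM (-1.86 ± 0.27, adjusted p = 6.28e-07). The library labelled mature CD45 KO replicate 1 held 238 CPM of Ptprc (20 counts, 95% Poisson interval 146 to 368 CPM), against 253 to 541 CPM in the mature controls and 101 and 88.0 CPM in the other 2 libraries of its group. The labels do not say which part of Ptprc was deleted, and oligo-dT priming samples the 3' ends of transcripts, so remaining counts do not measure functional transcript.

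**Figure D1:**
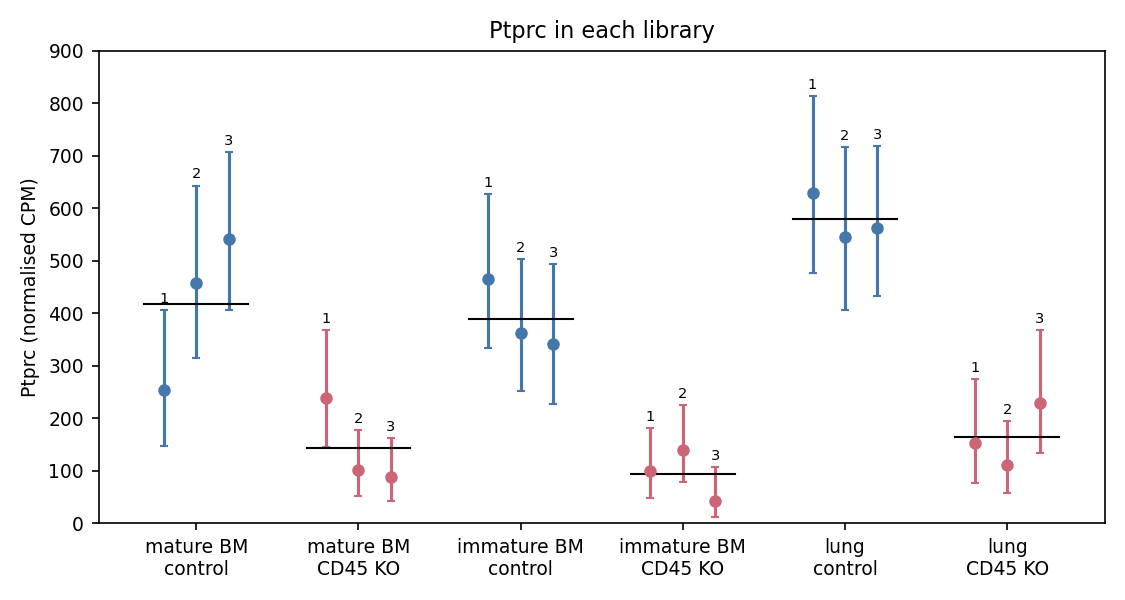
Normalised CPM of Ptprc in each of the 18 libraries (points, numbered by replicate), with 95% Poisson intervals for counting error and a black line at each group mean. Among the bone marrow CD45 KO libraries, the one labelled mature replicate 1 lies highest, at 238 CPM.

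CD45 loss in mature bone marrow ILC2 was compared with control to ask what the phosphatase does in the differentiated marrow cell. Besides Ptprc, 4 genes passed the test. Ccr2, a chemokine receptor, rose from 345 ± 54.8 to 742 ± 288 CPM (1.04 ± 0.22, adjusted p = 0.00697), and Slfn2, a Schlafen family gene, rose from 38.5 ± 14.8 to 160 ± 22.1 CPM (2.06 ± 0.47, adjusted p = 0.0143). The other 2, Serpina3g, a serine protease inhibitor (1.38 ± 0.33, adjusted p = 0.0324), and Malat1, a nuclear long noncoding RNA (-0.66 ± 0.15, adjusted p = 0.0126), were chosen for naming after their values were seen, because their groups of libraries overlapped. Areg, which encodes the epithelial growth factor amphiregulin, was at 4.97 ± 8.60 CPM in control and 58.6 ± 56.7 CPM in CD45 KO libraries and did not pass (3.47 ± 0.92, adjusted p = 0.0578).

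In mature ILC2, 0 of the 22 gene lists passed by camera, with the preset or an estimated correlation, and 5 were at an unadjusted p under 0.05 with the preset correlation. By fry 1 list passed, markers of blood progenitors (lower, 4 tested members, adjusted p = 0.00508). Of 11 tested members of the interferon response list, 8 had positive fold changes, 0 passed over all genes and 4 were higher adjusted over the list alone, with a list test at adjusted p = 0.116 and 0.29 with an estimated correlation. Gbp7, an interferon-induced GTPase, was at 253 ± 26.0 CPM in control and 422 ± 102 CPM in CD45 KO (0.72 ± 0.24, adjusted p = 0.238). The library labelled mature CD45 KO replicate 1 held 3288 CPM over the interferon list, against 4195 and 4514 CPM in the other 2 libraries of its group and 3469 to 3651 CPM in control. Without it the interferon list was higher in CD45 KO by camera (adjusted p = 0.0198). The lists of oxidative phosphorylation genes (0.0259, higher) and ILC progenitor genes (0.0376, lower) also passed. That fit used the preset correlation only. The library left out had the lowest interferon sum of the mature libraries, so leaving it out favours the interferon call. Ccr9, a gut-homing chemokine receptor, was at 191 CPM in that library and at 665 and 704 CPM in the other 2, against 833 to 969 CPM in control, and did not pass (-0.69 ± 0.20, adjusted p = 0.106).

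The count for mature ILC2 was 5 genes (3 higher, 2 lower) of 1916, and the groups of libraries did not overlap for 245 genes, 12.8% against the 10% that chance gives. The count was 12 without the library labelled CD45 KO replicate 1, with 4 of the 5 genes among them, 3 without CD45 KO replicate 3, and 0 when only the 6 mature libraries were fitted. Ccr2 lost its call without control replicate 2 or the library labelled CD45 KO replicate 1 (highest adjusted p = 0.117) and Slfn2 without control replicate 1, control replicate 3 or CD45 KO replicate 3 (highest 0.161). Malat1 lost it without control replicate 2 or 3 or CD45 KO replicate 2 or 3 (highest 0.233), and Serpina3g without control replicate 1 or 3 or CD45 KO replicate 2 or 3 (highest 0.257).

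In immature bone marrow ILC2, the precursor stage, 32 genes passed between CD45 KO and control, 21 higher and 11 lower. The larger increases included interferon-inducible GTPases. Iigp1 rose from 37.8 ± 28.0 to 211 ± 78.7 CPM (2.48 ± 0.48, adjusted p = 0.000787) and Igtp from 86.1 ± 12.8 to 277 ± 25.4 CPM (1.69 ± 0.33, adjusted p = 0.000787). Ms4a6b, a 4-transmembrane surface protein gene, rose from 48.3 ± 25.3 to 214 ± 18.5 CPM (2.12 ± 0.40, adjusted p = 0.000705). Il1rl1, which encodes the interleukin 33 receptor ST2 that activates ILC2, fell from 1502 ± 45.3 to 917 ± 108 CPM (-0.71 ± 0.15, adjusted p = 0.00298). Malat1 fell from 4531 ± 114 to 2705 ± 557 CPM (-0.74 ± 0.15).

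Interferon response genes rose as a group in immature CD45 KO ILC2. Of 11 tested members, 3 passed, among them Iigp1 and Igtp, and 5 were higher adjusted over the list alone, with 8 positive fold changes and a median of 0.59. The list test gave adjusted p = 0.0005, and adjusted p = 0.0116 with an estimated correlation. Targets of NF-kB, the transcription factor that drives inflammatory gene expression, fell as a group: all 13 tested members had fold changes of 0 or below, with a median of -0.56 (adjusted p = 0.0005, and 0.0116 with an estimated correlation). The NF-kB list lost its call without a filter on low counts (adjusted p = 0.302). Among its members Tnfaip3, which encodes the feedback inhibitor A20, passed over all genes (-1.51 ± 0.37, adjusted p = 0.0115).

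Smaller shifts were seen in 5 further lists, and none of these held with an estimated correlation. Oxidative phosphorylation genes were higher, with 31 of 37 tested members positive and a median of 0.22 (adjusted p = 0.00157, and 0.125 with an estimated correlation), but 0 members passed singly. ILC progenitor genes were lower, 7 of 10 without a positive fold change (adjusted p = 0.0108, and 0.123 with an estimated correlation), with Satb1, a chromatin organiser, past the threshold (-1.03 ± 0.29, adjusted p = 0.0499). Proliferation genes were higher (adjusted p = 0.0108, and 0.123 with an estimated correlation), led by the tubulin gene Tuba1b (1.17 ± 0.23), as were antigen presentation genes (0.0142, and 0.123) and unfolded protein response genes (0.0302, and 0.245), the last with the chaperone gene Hsp90b1 (0.90 ± 0.24). Without CD45 KO replicate 1 the progenitor list was at adjusted p = 0.122, without CD45 KO replicate 2 the proliferation list at 0.106, and without control replicate 1 the antigen presentation list at 0.0584. The proliferation and antigen presentation lists were at 0.0665 when only the immature libraries were fitted.

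Other genes that passed in immature ILC2 were Vim, encoding the filament protein vimentin (1.20 ± 0.27), Pim1, a kinase gene induced by STAT signalling (1.13 ± 0.31), Serpina3g (1.42 ± 0.35), Ptpn9, a tyrosine phosphatase gene (1.70 ± 0.44), and Hsp90aa1 (0.86 ± 0.23). Lower genes were Lmo4, a transcriptional cofactor gene (-0.76 ± 0.17), Zfp36l2, which encodes an mRNA decay factor (-0.81 ± 0.19), and Rora, a transcription factor needed for ILC2 development (-0.82 ± 0.23). Gata3 (-0.25 ± 0.13, adjusted p = 0.448), Il7r (-0.52 ± 0.19, adjusted p = 0.171), Kit (-1.41 ± 0.46, adjusted p = 0.119) and Bcl2 (0.61 ± 0.26, adjusted p = 0.272) did not pass.

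Groups did not overlap for 343 genes in immature ILC2, 17.9% against 10% by chance. The count of 32 was 12 without control replicate 1, 13 without control replicate 2, 19 without control replicate 3 and 21 without CD45 KO replicate 2, and 7 of the 18 genes named as passing kept their call with each library left out (Ptprc, Ms4a6b, Iigp1, Igtp, Tuba1b, Malat1 and Il1rl1). Tnfaip3 lost its call without control replicate 1 or CD45 KO replicate 1 or 2 (highest adjusted p = 0.101), and Satb1 without any 1 of the 6 libraries (highest 0.355). Lmo4, Vim, Zfp36l2, Serpina3g, Ptpn9, Pim1, Rora, Hsp90b1 and Hsp90aa1 also lost the call with at least 1 library left out. Their highest adjusted p lay between 0.0535 (Vim) and 0.309 (Rora).

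**Figure D2:**
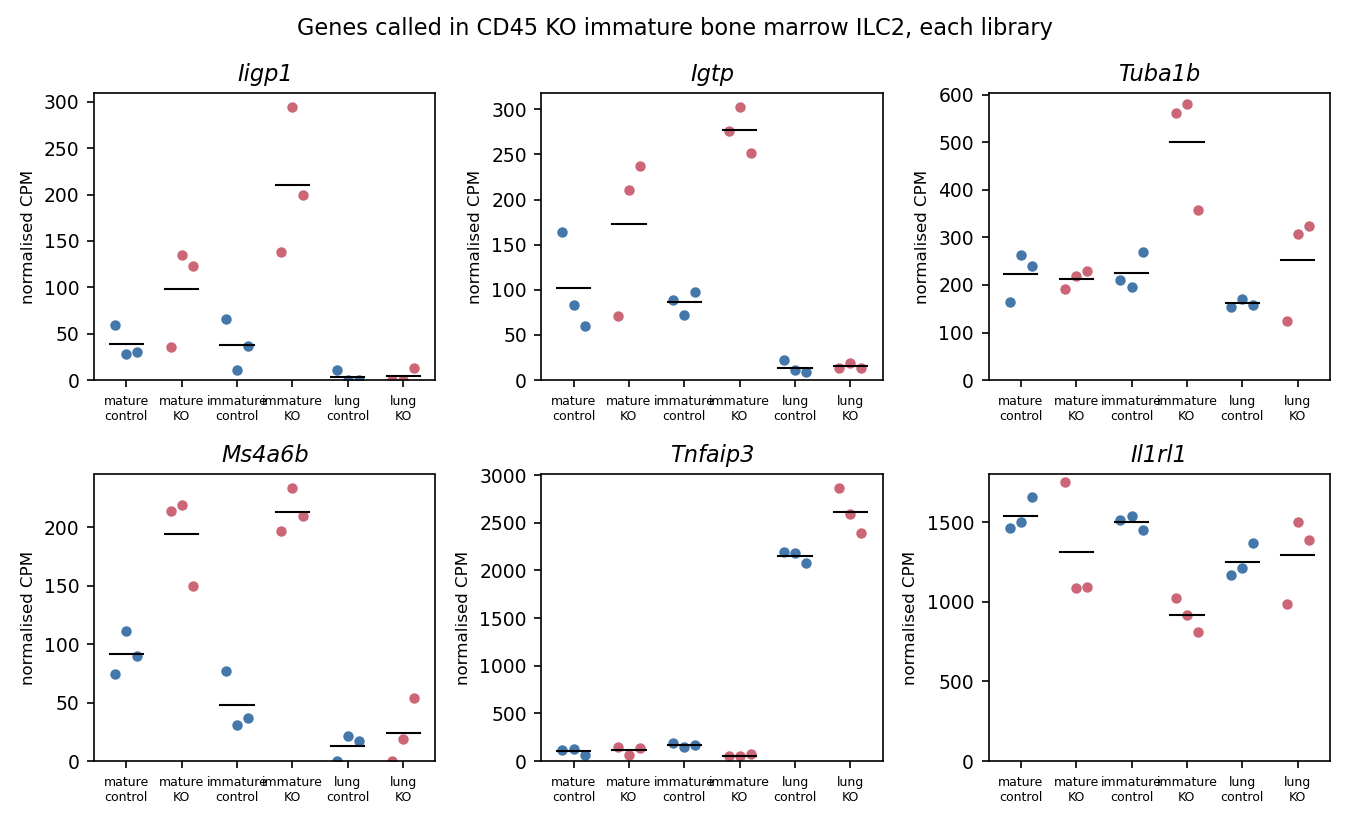
Normalised CPM of 6 genes that passed the test in immature CD45 KO ILC2, in each library of the 6 groups (points) with group means (black lines). Iigp1 averaged 37.8 CPM in immature controls and 211 CPM in immature CD45 KO libraries, and Tnfaip3 averaged 168 and 58.2 CPM.

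In lung ILC2, the tissue-resident population, 48 genes passed between CD45 KO and control, 39 higher and 9 lower. Egr1, an immediate-early transcription factor gene, rose from 127 ± 18.6 to 612 ± 136 CPM (2.24 ± 0.28, adjusted p = 8.81e-09), and the nuclear receptor gene Nr4a3 from 578 ± 84.7 to 1241 ± 172 CPM (1.11 ± 0.17, adjusted p = 1.93e-06). The type 2 cytokine gene Il5 rose from 585 ± 116 to 1028 ± 279 CPM (0.86 ± 0.19, adjusted p = 0.00191) and Il13 from 105 ± 80.1 to 276 ± 64.5 CPM (1.42 ± 0.40, adjusted p = 0.0346). The chemokine gene Ccl1 rose from 640 ± 86.9 to 1143 ± 187 CPM (0.84 ± 0.17, adjusted p = 0.000612).

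Immediate-early and dissociation genes were higher as a group in lung CD45 KO ILC2 with the preset correlation, but not with an estimated correlation (adjusted p = 0.0598): 22 of 25 tested members had positive fold changes, with a median of 0.42, 5 passed (Egr1, Nr4a3, Fosb, Jund and Nr4a1), and adjusted over the list alone 13 were higher and 2 lower. The list test with the preset correlation gave adjusted p = 2.21e-05. Fosb rose from 1403 ± 202 to 2324 ± 253 CPM (0.73 ± 0.13, adjusted p = 0.000151). Of 13 tested effector genes, 3 passed (Il5, Il13 and Ccl1) and 7 were higher adjusted over the list alone, with a list test at adjusted p = 0.0683 and 0.112 with an estimated correlation. Areg (0.48 ± 0.15, adjusted p = 0.0614), Csf2 (0.38 ± 0.15, adjusted p = 0.177) and Arg1 (0.44 ± 0.17, adjusted p = 0.168) did not pass.

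Ribosomal protein genes were higher by a small amount, with 75 of 81 members positive and a median of 0.28. Of these 6 passed, for example Rps15a (0.57 ± 0.12) and Rps7 (0.51 ± 0.12), and 29 were higher adjusted over the list alone (adjusted p = 2.43e-11, and 0.242 with an estimated correlation). NF-kB targets were higher, 11 of 13 positive (adjusted p = 0.0117, and 0.0761 with an estimated correlation), with Nfkbiz (0.64 ± 0.14) and Nfkb1 (0.65 ± 0.17) passing. Lung ILC2 tissue genes (adjusted p = 0.00453), glucocorticoid response genes (0.0158), antigen presentation genes (0.0333) and glycolysis and hypoxia genes (0.0433, with Ldha at 0.72 ± 0.17) were higher, and interferon response genes lower (0.0433, median -0.34, 0 members passing). Each of these 5 lists was at adjusted p = 0.112 with an estimated correlation. Without control replicate 3 the NF-kB and antigen presentation lists were at adjusted p = 0.0525. The glycolysis list lost its call without control replicate 1 or 3 or any 1 CD45 KO replicate (highest 0.373), and the interferon list without control replicate 1 or 3 or CD45 KO replicate 1 or 2 (highest 0.118). Without a filter on low counts the interferon list turned to the other direction (adjusted p = 0.984) and the glycolysis list was at 0.138. With only the lung libraries fitted, the interferon and antigen presentation lists were at 0.429 and the glycolysis list at 0.149.

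Among other genes that passed in lung CD45 KO ILC2, the interferon gamma receptor gene Ifngr1 (1.12 ± 0.22), Ly6a, encoding the surface antigen Sca-1 (1.07 ± 0.22), the costimulatory receptor gene Icos (0.56 ± 0.15), the selectin ligand gene Selplg (0.78 ± 0.20) and the inhibitory receptor gene Lilrb4a (1.17 ± 0.35) were higher, as were the transcription factor gene Ets2 (1.44 ± 0.33) and Alox5, encoding the first enzyme of leukotriene synthesis (1.32 ± 0.35). The hyaluronan receptor gene Cd44 (-0.69 ± 0.17), the syndecan gene Sdc4 (-1.58 ± 0.37), the transcription factor gene Maf (-0.99 ± 0.29), the pseudogene Pisd-ps3 (-1.42 ± 0.28), whose counts can be shared with its parent gene, and Cd52 (-0.54 ± 0.16) were lower.

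Groups did not overlap for 377 genes in lung, 19.7% against 10% by chance, and the count of 48 was 31 without control replicate 1, 29 without control replicate 2 and 29 without control replicate 3. Of 31 passing genes followed with each library left out, 13 kept their call throughout, among them Egr1, Nr4a3, Fosb, Ccl1, Ly6a and Ifngr1. Il5 lost it without CD45 KO replicate 2 (adjusted p = 0.132) and Il13 without control replicate 1 or 3 or CD45 KO replicate 2 or 3 (highest 0.347). Ldha, Sdc4, Cd44, Nfkb1, Selplg, Nr4a1, Icos, Alox5, Maf, Lilrb4a and Cd52 also lost the call with at least 1 library left out. Their highest adjusted p lay between 0.0765 (Ldha) and 0.432 (Cd52). Rps10, Rpl13, Dhx40, Syne1 and Rgs1, passing genes not named above, lost it too, with a highest adjusted p between 0.0561 (Rps10) and 0.740 (Rgs1).

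**Figure D3:**
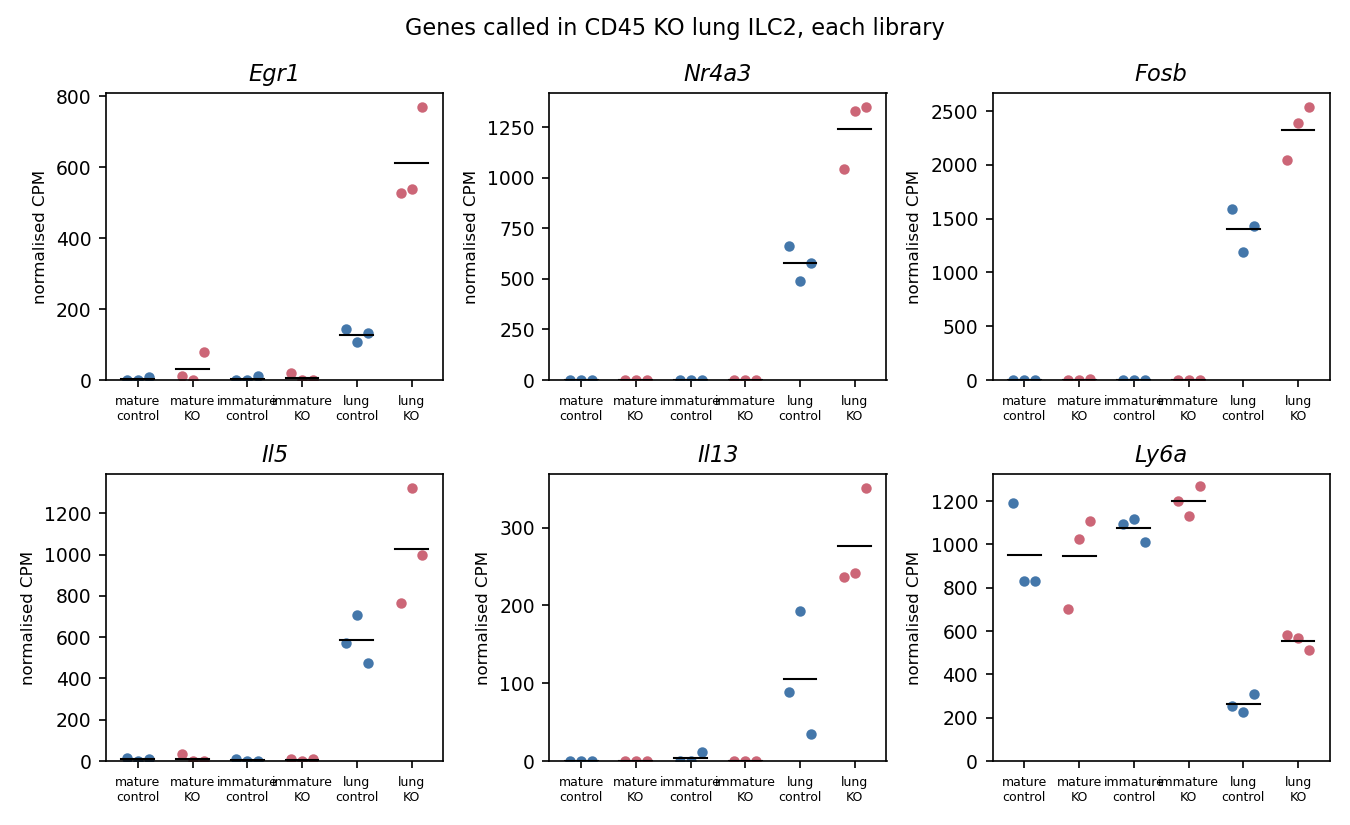
Normalised CPM of 6 genes that passed the test in lung CD45 KO ILC2, in each library of the 6 groups (points) with group means (black lines). Egr1 averaged 127 CPM in lung controls and 612 CPM in lung CD45 KO libraries, and Il5 averaged 585 and 1028 CPM.

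Mature and immature bone marrow ILC2 of control mice were compared to find what separates the stages, and 1 gene passed. Klrg1, a lectin-like receptor gene that marks mature ILC2, was at 18.5 ± 16.3 CPM in immature and 230 ± 87.5 CPM in mature ILC2 (3.56 ± 0.53, adjusted p = 3.13e-06). The next smallest p-values belonged to Thy1 (-1.08 ± 0.29, adjusted p = 0.31), BC018473 (-1.15 ± 0.34, adjusted p = 0.64), Neb (1.49 ± 0.45, adjusted p = 0.64) and Tmem64 (1.07 ± 0.34, adjusted p = 0.781), none of which passed. Of the 22 gene lists 0 passed by camera, with the preset or an estimated correlation, or by fry, and 4 were at an unadjusted p under 0.05 by camera with the preset correlation. At an unadjusted p under 0.05 there were 103 genes, and groups did not overlap for 195 genes, 10.2% against 10% by chance.

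Lung and mature bone marrow ILC2 of control mice were compared to describe the tissue difference, in which 491 genes passed, 287 higher and 204 lower in lung. The first principal component of log2 CPM held 67.8% of the variance and separated lung from bone marrow libraries. Several immediate-early genes had 0 or few counts in mature controls. Fosb had 0 counts in mature controls and 1403 ± 202 CPM in lung controls, at least 112-fold higher against a limit of 3 counts over the group, and Nr4a1 rose from 16.3 ± 3.31 to 2358 ± 428 CPM (7.03 ± 0.31, adjusted p = 2.84e-34). Of 25 tested members of the immediate-early and dissociation list 20 were higher and 1 lower (adjusted p = 3.27e-17, and 0.000162 with an estimated correlation). Any difference in cell preparation between lung and bone marrow was not tested. It cannot be told apart from tissue for any gene or list of this comparison. Nr4a3, Nr4a2 and the chemokine gene Cxcl2 had 0 counts in mature controls and were at least 46.0, 28.6 and 98.6-fold higher in lung.

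Effector genes of ILC2 were higher in lung as a group, 10 of 13 higher and 1 lower (adjusted p = 5.8e-10, and 0.000162 with an estimated correlation). Areg rose from 4.97 ± 8.60 to 1259 ± 121 CPM (7.84 ± 0.44), Il5 from 8.31 ± 7.60 to 585 ± 116 CPM (5.90 ± 0.49) and Csf2 from 44.2 ± 16.2 to 931 ± 36.7 CPM (4.30 ± 0.29). Il13 and Ccl1 had 0 counts in mature controls and were at least 8.02 and 51.6-fold higher. NF-kB targets were higher, 8 of 13 passing (adjusted p = 3.22e-05, and 0.00367 with an estimated correlation), with Tnfaip3 at 4.46 ± 0.22 and Nfkbia at 1.95 ± 0.16. Tissue repair genes (5 of 8 passing, adjusted p = 1.23e-05, and 0.00646 with an estimated correlation), including Lgals1 and Furin, and lung ILC2 tissue genes (13 of 19 higher and 2 lower, adjusted p = 7.58e-08, and 0.00905 with an estimated correlation), including Rgs2 (8.05 ± 0.34) and Cd69 (3.13 ± 0.44), were also higher.

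Interferon response genes were lower in lung, 7 of 11 passing with a median of -1.20 (adjusted p = 0.000798, and 0.00905 with an estimated correlation). Ifi47 fell from 195 ± 15.8 to 23.2 ± 10.9 CPM (-2.99 ± 0.47) and Irgm1 from 158 ± 23.2 to 22.6 ± 12.2 CPM (-2.69 ± 0.52). Antigen presentation genes were lower, 4 of 9 passing (adjusted p = 0.000943, and 0.0188 with an estimated correlation), with Tap1 at -2.18 ± 0.45 and Cd74 at -3.21 ± 0.74. Ribosomal protein genes were lower, 42 of 81 passing with a median of -0.34 (adjusted p = 4.43e-08, and 0.43 with an estimated correlation). The list of migration and adhesion genes did not pass (6 of 14 higher and 3 lower, adjusted p = 0.801, and 0.876 with an estimated correlation). Of single genes, Ccr9 fell from 881 ± 75.9 to 21.8 ± 22.0 CPM (-5.35 ± 0.39) and the integrin gene Itga4 by a log2 change of -1.71 ± 0.26, whereas Ccr2 (2.18 ± 0.19) and Cd44 (3.55 ± 0.25) were higher.

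Of the ILC2 identity list, Rora (2.18 ± 0.19), Icos (1.95 ± 0.21) and Gata3 (0.63 ± 0.13) were higher in lung and Id2 (-1.23 ± 0.16) and Ly6a (-1.82 ± 0.20) lower, and the list as a whole did not pass (adjusted p = 0.564, and 0.839 with an estimated correlation). Kit, which is not in that list, was higher (1.85 ± 0.29). Klrg1 was lower in lung (-0.91 ± 0.34, adjusted p = 0.0376) but lost the call without mature control replicate 2 or 3 or lung control replicate 1, 2 or 3 (highest adjusted p = 0.219). Xist had 0 counts in mature controls and 888 ± 105 CPM in lung, and the Y-linked gene Ddx3y 131 ± 37.5 CPM in mature controls and 0 counts in lung, so the sex of the animals cannot be told apart from tissue in this comparison. Without genes on chromosomes X and Y, an alternative chosen after seeing the data, 476 genes passed.

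Whether the effect of CD45 loss itself differed between populations was tested as a difference of effects. Lmo4 moved in opposite directions: it was higher in lung CD45 KO ILC2 and lower in immature CD45 KO ILC2, with a difference of 1.60 ± 0.22 between lung and immature (adjusted p = 3.87e-07) and 1.51 ± 0.22 between lung and mature ILC2 (adjusted p = 3.82e-06). Between lung and immature ILC2, 7 genes passed (3 higher and 4 lower in their difference), and between lung and mature ILC2 6 genes (3 and 3). Tnfaip3 (1.80 ± 0.39) and Satb1 (1.96 ± 0.48) had higher effects in lung than in immature ILC2, and Vim (-1.45 ± 0.32), S100a4 (-1.29 ± 0.28) and Hsp90aa1 (-1.54 ± 0.36) lower effects. Sex differed between lung and bone marrow animals as above, so it cannot be told apart from tissue in these differences either.

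NF-kB targets had a higher effect in lung than in immature ILC2 (12 of 13 positive, median 1.03, adjusted p = 5.23e-06, and 0.00308 with an estimated correlation) and interferon response genes a lower effect (1 of 11 positive, median -1.02, adjusted p = 1.11e-05, and 0.00308 with an estimated correlation). Between mature and immature ILC2 0 genes passed by edgeR's or DESeq2's test, with 94 at an unadjusted p under 0.05 by edgeR. Tnfaip3 (1.75 ± 0.52), Tuba1b (-1.24 ± 0.37) and Pxdc1 had the smallest p-values there, each at adjusted p = 0.761. Across 1915 genes without Ptprc, CD45 effects in mature and immature ILC2 correlated at r = 0.252 (Spearman rho = 0.283), those in mature and lung ILC2 at r = 0.0699 (rho = 0.0462) and those in immature and lung ILC2 at r = 0.0334 (rho = 0.0319), across genes, which are not independent replicates. Of the 31 genes other than Ptprc that passed in immature ILC2, 24 had the same sign in mature ILC2 and 16 in lung ILC2.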

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

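The tests of explanations in this part were chosen after the results they bear on had been seen, and the tests of differences between CD45 effects were planned. The results listed here stood out because the effect of CD45 loss differed between populations by a direct test of the difference.

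Between lung and mature ILC2 the CD45 effects differed for 6 genes (log2, lung minus mature, edgeR). The differences were 1.51 for Lmo4 (adjusted p = 3.82e-06), -2.25 for Pisd-ps3 (0.00815), and, each at 0.0461, -2.32 for Rexo2, -1.06 for Ccr2, 0.86 for Actg1 and 1.05 for Nfkb1. Lmo4 kept its call with each of the 12 libraries left out. Pisd-ps3 lost it without mature control replicate 1 or CD45 KO replicate 3 (highest adjusted p = 0.0855). Rexo2 kept it only without the library labelled mature CD45 KO replicate 1, mature CD45 KO replicate 3 or lung CD45 KO replicate 1 (highest 0.128). Ccr2 kept it only without mature CD45 KO replicate 2 or 3 or lung CD45 KO replicate 2 (highest 0.236). Actg1 kept it only without mature control replicate 2 or mature CD45 KO replicate 2 or 3 (highest 0.153). Nfkb1 kept it only without the library labelled mature CD45 KO replicate 1 or lung control replicate 2 (highest 0.131).

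Of the 22 lists, 4 differed between lung and mature ILC2. Ribosomal protein genes (adjusted p = 5.08e-09), immediate-early genes (0.00352) and markers of blood progenitors (0.00703, 4 tested members) had higher effects in lung. Interferon response genes had lower effects (0.00413). With an estimated correlation none of the 4 passed: they were at 0.432, 0.109, 0.0732 and 0.0732. Interferon response genes also lost the call without a filter (0.352). The library labelled mature CD45 KO replicate 1 enters all differences with mature ILC2, and sex enters all differences between lung and bone marrow.

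Between lung and immature ILC2 the CD45 effects differed for 7 genes (log2, lung minus immature, edgeR). Among them the differences were 1.60 for Lmo4 (adjusted p = 3.87e-07), 1.80 for Tnfaip3 and -1.29 for S100a4 (both 0.00646), -1.45 for Vim (0.00865), -1.54 for Hsp90aa1 (0.0144) and 1.96 for Satb1 (0.0319). Lmo4 kept the call with each of the 12 libraries left out. Without immature control replicate 1 the other 5 named here lost it. Tnfaip3, S100a4, Hsp90aa1 and Satb1 lost it without immature CD45 KO replicate 1, and S100a4 and Vim without immature control replicate 2. Leaving out lung control replicate 1 ended it for Vim and Satb1, lung control replicate 3 and CD45 KO replicate 1 for Hsp90aa1 and Satb1, and lung CD45 KO replicate 2 for Satb1. The highest adjusted p were 0.0818, 0.102, 0.0839, 0.178 and 0.146 for Tnfaip3, S100a4, Vim, Hsp90aa1 and Satb1.

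Of the 22 lists, 8 differed between lung and immature ILC2. Higher effects in lung were found for ribosomal protein genes (adjusted p = 1.5e-07), NF-kB targets (5.23e-06), immediate-early genes (0.00521), glucocorticoid response genes (0.0129), lung ILC2 tissue genes (0.0268) and blood progenitor markers (0.0349). Lower effects were found for interferon response genes (1.11e-05) and unfolded protein response genes (0.0349). With an estimated correlation, NF-kB targets and interferon response genes kept the call (both 0.00308), and the other 6 lists were at 0.113 to 0.344. Lung ILC2 tissue genes lost the call without immature control replicate 2, immature CD45 KO replicate 1 or lung CD45 KO replicate 2 (highest 0.0924). Blood progenitor markers lost it without 7 of the 12 libraries (highest 0.0924) and unfolded protein response genes without 6 (highest 0.269). Without a filter these 2 lists were at 0.178 and 0.159, and with the stricter filter unfolded protein response and glucocorticoid response genes were at 0.0573.

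Between mature and immature ILC2, NF-kB targets had a higher effect in mature ILC2 (adjusted p = 0.0255), but did not pass with an estimated correlation (0.107). The call was lost without mature control replicate 1 or 2, mature CD45 KO replicate 3, the library labelled mature CD45 KO replicate 1, or immature control replicate 2 or 3 (highest 0.169). It was also lost without a filter (0.25), with the stricter filter (0.0652) and with only the libraries of the contrast (0.527). Without Rn45s and Rn4.5s, 0 lists passed for this difference.

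The interferon response list was higher in immature CD45 KO ILC2. Genes carried along with the deleted allele are argued against, since 0 of its 11 tested members lie within 20 Mb of Ptprc, and an effect of such genes on others was not tested. A trend with transcript length as the whole cause is argued against: after its removal from each library, which shifted genes by up to 0.20, camera's unadjusted p for the list was 4.81e-05 (4.47e-05 before) and the median of its members 0.56 (0.54 before). Cells of 6 other types (T, NK and ILC1, B lineage, neutrophil, monocyte and macrophage, erythroid and megakaryocyte) are argued against by their summed markers, which gained 0.0790 of the 1293 CPM that the interferon list gained, mostly through Ccl5 (34 counts in control, 66 in CD45 KO), while ILC3 markers, outside that sum, gained 26.0 CPM and were higher in each CD45 KO library. A response to CD45 loss, or another difference between the animals, stays open as a hypothesis.

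The library labelled mature CD45 KO replicate 1 lay apart from the other 2 libraries of its group, and on the second principal component of the bone marrow libraries apart from mature controls too (-13.4, mature controls -0.652 to 5.28, other mature CD45 KO libraries -0.950 and -1.75). Lung ILC2 in it are argued against, since 8 genes with no count in mature controls and many in lung summed to 1 count there and 528 to 659 in lung controls. Over the 31 genes other than Ptprc that passed in immature ILC2, with mature controls averaging 0 and the immature change 1, it lay at 0.106 (controls -0.0155 to 0.0137, other CD45 KO libraries 0.436 and 0.540). Ccr2 (1072 CPM, controls 291 to 401) and Slfn2 (143 CPM, controls 29.8 to 55.5) lay on the side of the other CD45 KO libraries. Both were named because the CD45 KO group, with this library in it, did not overlap control. Their position therefore does not argue against control cells. In this library Rn45s made up 16.1% of counts (8.73% to 10.7% in the other mature libraries) and Rn4.5s 4.17% (6.95% to 8.81%). What these shares reflect was not tested. Control cells under this label and a trend with transcript length (rho = 0.331 across 1208 genes, against up to 0.253 in size in other groups) stay open. They cannot be told apart with 1 library, and no biological explanation was tested.

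The immediate-early list was higher in lung CD45 KO ILC2 with the preset correlation, but not with an estimated correlation (adjusted p = 0.0598). A single library as the cause is argued against, since with each of the 6 libraries left out the highest adjusted p was 0.000427 (without CD45 KO replicate 2). A trend with transcript length as the whole cause is argued against: after its removal, which shifted genes by up to 0.24, camera's unadjusted p was 4.49e-06 (1.99e-06 before) and the median of the members 0.32 (0.39 before). Stronger stress from handling in the CD45 KO sorts stays open: only 2 heat shock members were tested (median log2 fold change -0.27), too few to decide. A response to CD45 loss stays open as untested.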

How the results depend on the processing

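Fits without Rn45s and Rn4.5s, without 2 mature replicate 1 libraries and without genes on chromosomes X and Y were chosen after seeing the data. Under the size factors of DESeq2 and the stricter filter, every gene count stayed within 1.5 times its value, with 54 and 55 genes in lung. For lung minus mature ILC2, both split the 6 calls 4 higher and 2 lower in place of 3 and 3. The other settings moved some counts of passing genes, and the cause was not tested unless stated. With the test of DESeq2 the counts were 2 (mature CD45 KO), 6 (immature), 14 (lung), 1 (lung minus mature effect) and 3 (lung minus immature effect), and 348 between lung and mature ILC2. Without a filter, 22 genes passed in lung CD45 KO and 4 between stages. With only the libraries of the contrast, a fit with fewer samples, the counts were 0 (mature CD45 KO), 3 (stages), 2 (lung minus mature effect) and 13 (lung minus immature effect). Without mature control replicate 1 and the library labelled mature CD45 KO replicate 1 together, lung minus mature gave 3. Against 36 list calls, an estimated correlation gave 11 and fry 45. Without a filter 29 of the list calls held, 6 ended and 1 turned, with only the libraries of the contrast 30 held and 6 ended, and with the stricter filter 33 held and 3 ended.

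Leaving out single libraries gave 3 to 12 genes in mature, 12 to 26 in immature and 29 to 42 in lung CD45 KO, 1 between stages, 393 to 452 between lung and mature ILC2, and 1 to 13, 0 and 2 to 9 for the differences of lung minus mature, mature minus immature and lung minus immature effects. The interferon list in lung CD45 KO reversed without a filter (adjusted p = 0.984). A part of the passing genes was followed through these settings, and not all of them are named in the text. The DESeq2 test ended 48 of their calls and left 68. Leaving out libraries ended 178 and left 651, all with the same sign. Fits without Rn45s and Rn4.5s gave 27 genes in immature and 51 in lung CD45 KO and 34 list calls. At the real depth and 3 libraries per group, simulated 2-fold changes were recovered for 41.3% to 44.9% of changed genes tested between CD45 KO and control, and the share due to depth was not tested. Alternatives with ERCC factors were not run because the table has 0 ERCC entries.

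Replicate numbers were checked for pairing: same-number correlations of deviations from the group means ranged from -0.109 to 0.105, and 0 of 15 group pairs had all above 0.1. No pairing by number was seen, but counting error at this depth can hide it, so pairing is not excluded. With the replicate block, counts were 6, 30 and 44 in mature, immature and lung CD45 KO, 1 between stages, 490 for lung vs mature BM ILC2, control, and 9, 0 and 7 for the differences of effects, with 39 list calls.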

Other observations

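The tests on other splits of the libraries were chosen after the results had been seen, and the genes and libraries singled out here were chosen after their values were seen. In immature CD45 KO ILC2 the interferon-inducible GTPase genes Tgtp2 (log2 fold change 1.12) and Tgtp1 (0.85), near-identical copies whose counts are uncertain, were among the passing genes outside the fixed lists, as were S100a4 (0.95), the actin-binding gene Tmsb4x (0.56) and the small GTPase gene Cdc42 (0.89). In lung CD45 KO ILC2 the actin gene Actg1 (0.89), the proteoglycan gene Srgn (0.78) and the costimulatory receptor gene Cd27 (2.06) passed. Src-family kinases are the best-known targets of CD45, and 9 of the 29 genes listed for them and their regulators were tested. Their RNA did not move as a list: 0 of the 9 passed in mature, immature or lung CD45 KO ILC2 (adjusted p of the list 0.78, 0.645 and 0.876). RNA levels do not measure the activity of these kinases.

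The second principal component of log2 CPM lay between 3.23 and 6.19 in the 6 bone marrow control libraries and between -8.43 and -4.42 in 5 of the 6 bone marrow CD45 KO libraries. In the library labelled mature CD45 KO replicate 1 it had the sign of the controls, while on the second component of the bone marrow libraries alone that library lay apart from mature controls and mature CD45 KO libraries alike (-13.4, mature controls -0.652 to 5.28, other mature CD45 KO libraries -0.950 and -1.75). Markers of other cell types were few: mature control replicate 1 held 195 counts of neutrophil markers against 1 to 13 in the other 11 bone marrow libraries, and lung CD45 KO replicate 1 held 30 counts of monocyte and macrophage markers against 2 to 6 in the other 5 lung libraries. Lung CD45 KO replicate 2 held 368 counts of proliferation genes against 143 to 218 in the other lung libraries. Markers of ILC3 summed to 27, 36 and 46 counts in lung controls and 12, 27 and 14 in lung CD45 KO.

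With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so these counts are given only with the highest of the other splits. Every other split mixes libraries of the 2 groups, and the spread was estimated again for each split. A real difference then widens the spread within the mixed groups. Few genes passing in the other splits therefore do not show what chance alone would give. In mature CD45 KO 5 genes passed (other splits up to 4; 1 of 10 as large) and 0 lists (up to 3; 10 of 10). In immature CD45 KO 32 genes (up to 3) and 7 lists (up to 2) passed, and in lung CD45 KO 48 genes (up to 1) and 8 lists (up to 1). Between stages 1 gene (up to 0) and 0 lists (up to 2) passed, and between lung and mature ILC2 491 genes (up to 0) and 8 lists (up to 8, 2 of 10 as large).

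For the differences of effects 100 splits were drawn. For each difference, all but the real split and 1 with labels exchanged in 1 population mixed KO and control libraries within a population. Mixing weakens the CD45 effects themselves, so these splits do not show what equal effects in the populations compared would give. A low share therefore cannot exclude chance for a difference of effects. Chance was not excluded for lung minus mature ILC2, where 6 of 100 splits gave at least the real 6 genes (others up to 18) and 5 of 100 at least the real 4 lists (up to 9). For mature minus immature ILC2 chance was not excluded for the 1 list (55 of 100 splits, up to 7), and with 0 genes passing all 100 splits gave as many by construction (up to 57), which decides nothing. For lung minus immature ILC2, 3 of 100 splits gave 7 genes or more (up to 26) and 1 of 100 gave 8 lists (highest other 5). The real split is counted in these shares. They are given without a conclusion, for the reason above. The splits with 18, 57 and 26 genes exchange KO and control labels in 1 population, which turns a difference of effects into their sum, so they carry the structure of the CD45 effect itself.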
